A study of Mus musculus with 16 samples.

How the data were processed

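Total RNA of whole striatum was measured on Affymetrix Mouse Genome 430 2.0 arrays, a 1-colour design with biotin-labelled cRNA, in 4 genotypes with 4 biological replicates each, per the labels. The authors deposited 1 table of log2 probe-set values for 45101 probe sets on 16 arrays. RMA and the affy package are named in the submitters' processing notes, with no version, role or order. RMA corrects background, normalizes arrays to a common distribution and summarises the probes of a set, so a change shared by most genes would be removed from such values. The deposited log2 values run from 3.34 to 14.71. A version of the array's design and a genome build are not given in the sources used here. For arrays, the number per group is what limits precision: the median gene SD within a group was 0.0976 in wild type, 0.0658 in DREAM+/-, 0.0816 in R6/2 and 0.106 in R6/2 x DREAM+/- (log2). Correlations between replicates lay between 0.9899 and 0.9974, so no pair was identical.

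Groups and replicate numbers were taken from the sample titles. Probe sets were named through the platform annotation supplied with the data. Of the 45101, 34945 had exactly 1 gene symbol, 932 several, 9160 none in that annotation and 64 were controls; only those with 1 symbol were used. Of these, 99.42% were matched to a gene table by Entrez identifier and 0 symbols changed. For each of 18193 genes, the probe set with the highest mean over all arrays stood for the gene. Genes with a mean under the 40th percentile of probe-set means (5.944) were left out, which left 13011. That percentile is a filter on brightness, not a test of presence.

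The tests, gene lists, covariates, alternatives and the rule for named genes were chosen before the data were examined, apart from the cortical covariate, the Kv4 list without Kcnip3, the fit without both arrays that stand apart and the tests in the closing observations that are named there as chosen later. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on the log2 values, with 1 mean per genotype and all 16 arrays sharing 1 estimate of spread. Contrasts were R6/2 against wild type, R6/2 x DREAM+/- against DREAM+/-, DREAM+/- against wild type, R6/2 x DREAM+/- against R6/2, the interaction, and the DREAM+/- effect averaged over R6/2 status. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Kcnip3 was tested on each probe set in a fit over all single-symbol probe sets, so its adjusted p there differs from that in the gene-level fit.

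In all, 29 lists with 534 gene names were written from textbook knowledge of striatal and neighbouring cell types, Huntington's disease models, DREAM and ATF6; 485 of the names were on the array, 440 were tested, and some genes are on more than 1 list. Camera with a preset correlation of 0.01 tested 28 lists in 6 contrasts, 168 tests adjusted together; blood markers had only 1 tested gene. Camera with an estimated correlation and fry were run beside it. Fry asks whether a list moves 1 way on balance and does not compare it with other genes. Counts of members are given over all genes tested and adjusted over the list alone. Named genes were Kcnip3, the 10 highest and 10 lowest per contrast among genes that passed with no overlap between groups, up to 4 members per list and contrast by unadjusted p, and a fixed set of 20 striatal, stress and control genes; not each gene the rule allows is named.

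The R6/2 signature score is, per array, the mean over signature genes of the sign of the R6/2 effect times the log2 value, less the wild-type mean. Signature genes passed for the R6/2 effect averaged over both backgrounds, a choice that favours neither background. Scores were compared by exact two-sided permutation over 70 assignments, and the difference of differences over 4900 assignments within R6/2 status. Comparisons that share arrays were set beside 1000 simulations of unchanged groups and beside splits of the shared group. The share of changed genes near Kcnip3 was tested with Fisher's exact test, 2-sided.

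The limma step was tested on simulated data with independent normal noise, given each gene's mean over all arrays and its pooled spread. In these data 50 of 13011 genes were changed at each of 4 known sizes. Differences in spread between groups and correlation among genes were not simulated, so the shares that follow describe the simulated data. In R6/2 against wild type the limma step recovered 54.0% of changes of 0.3 (log2), 86.0% of 0.5 and 100% of 1, with 10 false calls among 180. In R6/2 x DREAM+/- against R6/2 it recovered 62.0%, 96.0% and 98.0% of those sizes (14 false of 192), and in DREAM+/- against wild type 60.0%, 94.0% and 98.0% (6 false of 182). In R6/2 x DREAM+/- against DREAM+/- it recovered 60.0%, 86.0% and 100% (8 false of 181), in the interaction 26.0%, 78.0% and 100% (8 false of 160), and in the averaged effect 82.0%, 100% and 100% (11 false of 202). A signature ratio of 0.8 was recovered as 0.809. Alternatives tried were other brightness filters, other ways to join probe sets, added normalization, array weights, trended and robust variance, fits of only the arrays compared, a replicate block, an Xist covariate, a 1.5-fold threshold, other signature choices and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.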

Results

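Gene expression was measured in striatum from 4 genotypes of mice of B6xCBA strain, with 4 biological replicates of each and 16 arrays in all. The genotypes were wild type, DREAM+/-, R6/2 and R6/2 crossed with DREAM+/-. R6/2 mice carry the first exon of human huntingtin with an expanded CAG repeat and are a model of Huntington's disease. DREAM, also called calsenilin, is a calcium-binding repressor of transcription that also binds Kv4 potassium channels. Its gene is Kcnip3. RNA came from whole striatum, so the values describe bulk tissue, although the labels name striatal neurons. Each sample was hybridized to an Affymetrix Mouse Genome 430 2.0 array, and the deposited values are log2 probe-set levels. The values ran from 3.34 to 14.71, and 13011 genes were bright enough to be tested. The 4 arrays per genotype limit the precision of each value.

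The R6/2 transgene and the DREAM genotype each separated the arrays. On the first principal component, 34.3% of the variance, the R6/2 arrays lay between 4.59 and 15.6 and the arrays without the transgene between -12.6 and -8.38. On the second, 25.1% of the variance, DREAM+/- arrays lay between -13.2 and -3.40 and the remaining arrays between 0.899 and 15.9. R6/2 x DREAM+/- replicate 3 stood apart on the third component at -15.9, where the others lay between -4.87 and 10.6. The female-specific transcript Xist read 6.49 in R6/2 replicate 1 and 11.04 to 12.16 in the other arrays. The Y-linked gene Eif2s3y read 8.91 in R6/2 replicate 1, where it was highest, 6.57 to 7.36 in the other R6/2 arrays, 6.16 and 6.46 in wild-type replicates 1 and 2, 7.80 and 7.55 in wild-type replicates 3 and 4, 7.51 to 8.05 in DREAM+/-, and 6.23 in R6/2 x DREAM+/- replicate 3 against 7.34 to 7.42 in the others of its group. Kdm5d, also Y-linked, read 5.24 and 5.25 in wild-type replicates 1 and 2, 6.57 and 6.24 in replicates 3 and 4, and 6.31 to 6.72 in DREAM+/-. These higher Y-linked levels came with Xist at 11.04 or above in every array but R6/2 replicate 1. The sex of the animals, and whether a sample held RNA of several animals, are not given in the sources used here, and a mixture of sexes was not tested. High Xist beside raised Eif2s3y and Kdm5d argues against RNA of 1 animal alone in the DREAM+/- arrays and in wild-type replicates 3 and 4. R6/2 x DREAM+/- replicates 1, 2 and 4 and R6/2 replicate 4 had the same pattern at lower levels, with Kdm5d at 5.70, 5.75, 6.06 and 5.79. Kdm5d read 4.94 in R6/2 x DREAM+/- replicate 3, 4.95 and 5.27 in R6/2 replicates 2 and 3, and 7.54 in R6/2 replicate 1. A mixed signal is thus not confined to DREAM+/- and wild type. Outside the DREAM+/- arrays and wild-type replicates 3 and 4, it is open whether each replicate is 1 animal.

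**Figure D1:**
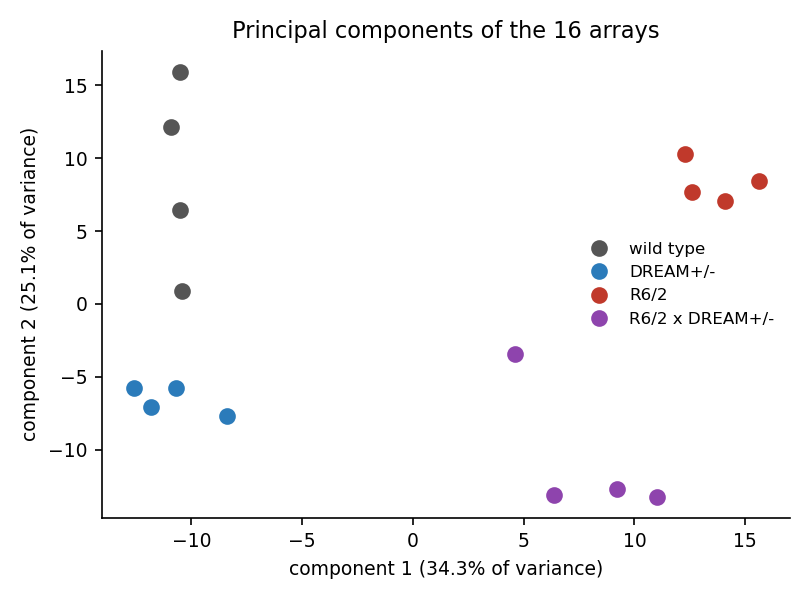
Scores of the 16 arrays on the first principal component (x axis, 34.3% of the variance) and the second (y axis, 25.1%), 1 point per array and 1 colour per genotype. R6/2 arrays lie right of 4 on the x axis, and arrays of DREAM+/- genotype lie below -3 on the y axis.

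Kcnip3, the targeted gene, fell in every DREAM+/- group on both of its probe sets. The brighter probe set read 9.67 ± 0.24 in wild type, 7.77 ± 0.04 in DREAM+/-, 9.11 ± 0.09 in R6/2 and 7.56 ± 0.12 in R6/2 x DREAM+/- (log2 mean ± SD, n = 4 each). Against wild type, DREAM+/- striatum held 26.9% of the level on this probe set and 13.0% on the dimmer. The dimmer probe set averaged 5.58 in DREAM+/- and read 5.24 to 5.57 in R6/2 x DREAM+/-, under the brightness filter of 5.944, so its percentages are set in part by background. The log2 changes were -1.90 (95% interval -2.09 to -1.70, limma adjusted p = 3.67e-09) and -2.95 (-3.20 to -2.69, adjusted p = 3.74e-10). Against R6/2, the crossed animals held 34.1% and 16.6%, with log2 changes of -1.55 (-1.75 to -1.35) and -2.59 (-2.85 to -2.34). Kcnip3 also fell in R6/2 against wild type, by 0.56 and 0.54 on the log2 scale (adjusted p = 0.000775 and 0.00688). Within DREAM+/- animals the R6/2 values were -0.21 and -0.18 and did not pass (adjusted p = 0.219 and 0.473). All of these intervals for the DREAM+/- genotype lie below -1, the value for a halved level. The deleted part of the gene is not given in the sources used here, so a probe set outside it would not check the genotype.

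**Figure D2:**
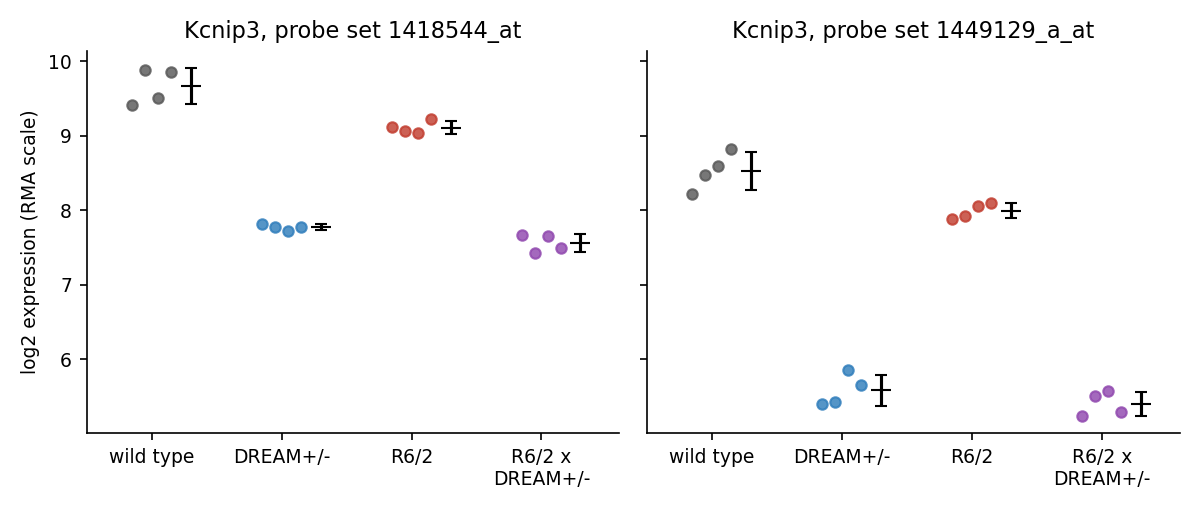
Log2 expression of Kcnip3 (y axis, RMA scale) on its brighter (left) and dimmer (right) probe set in the 4 genotypes, 1 point per array, with mean and SD beside the points (n = 4). Group means on the brighter probe set are 9.67, 7.77, 9.11 and 7.56 from left to right.

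The comparison of R6/2 with wild type asks what the transgene changed in striatum. Of 32 genes that mark medium spiny neurons, the main output cells of the striatum, 30 were lower, 0 higher and 2 did not pass. Their median log2 change was -0.62. The list passed camera (adjusted p = 9.49e-25), but not with an estimated correlation among genes (camera adjusted p = 0.0647). Penk (enkephalin) fell from 13.26 ± 0.05 to 12.36 ± 0.08 (log2, n = 4, adjusted p = 4.51e-07). Cnr1, the cannabinoid receptor, fell by 1.15 on the log2 scale (adjusted p = 6.71e-08). Arpp19 fell by 1.01 and Arpp21 by 0.79 on the log2 scale. Among receptors and peptides, Drd1 (dopamine receptor of the direct pathway) changed by -0.76, Drd2 (of the indirect pathway) by -0.78 and Pdyn (dynorphin) by -0.67. The signalling genes Ppp1r1b (DARPP-32) and Pde10a changed by -0.76 and -0.60. Tac1 (substance P) read 0.05 and did not pass (adjusted p = 0.549, 1 of 2 probe sets with that sign).

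Over all genes, limma called 3307 of 13011 changed at an adjusted p under 0.05, 1756 higher and 1551 lower. Of the 51 that changed at least 2-fold, 49 were lower. Egr2, an immediate early transcription factor, fell from 8.49 ± 0.44 to 5.80 ± 0.40 (log2, n = 4), a log2 change of -2.69 (SE 0.20, adjusted p = 1.03e-07). Abi3bp changed by -2.49, Crh (corticotropin-releasing hormone) by -2.26, Ryr1 (a calcium release channel) by -2.23, Ddit4l by -1.73 and Scn4b (a sodium channel subunit) by -1.48. Both genes up at least 2-fold were Sfmbt2, a Polycomb protein, at 1.26 (SE 0.14) and the transcript AW551984 at 1.20. Pcdh20 rose by 0.95, Asl by 0.91 and Gprasp2 by 0.83. In R6/2 Egr2, Abi3bp at 4.75 and Crh at 4.71 lay under the brightness filter of 5.944, as did Sfmbt2 in wild type at 5.85, so background sets part of these changes. Mouse Htt read 0.03 (adjusted p = 0.696).

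Genes of other lists were lower in R6/2, in several lists about as many as did not pass, and every list of this paragraph lost its camera call with an estimated correlation among genes (adjusted p = 0.0647 to 0.185). Of 23 immediate early genes, 19 were lower and 0 higher (median -0.80), among them Nr4a2 (-1.24, 5 of 6 probe sets with that sign), Egr1 (-0.82) and Homer1 (-0.64). Of 17 circadian clock genes, 10 fell and 0 rose (median -0.46), with Npas2 at -0.88, Hlf at -0.72 and Bhlhe40 at -0.58. Of 28 calcium handling genes 15 fell and 13 did not pass, the former including Camkk2 (-0.80). Of 24 glutamate receptor and postsynaptic genes 12 fell, including Shank3 (-0.64) and Gria3 (-0.42). Of 10 neurotrophin system genes 6 fell, including Bdnf (-0.36) and its receptor gene Ntrk2 (-0.36). Of 20 cholesterol synthesis genes 10 fell, including Msmo1 (-0.65), Cyp51 (-0.62) and Idi1 (-0.61). None of the genes on these last 4 lists rose. Of 14 genes reported as DREAM targets 9 fell and 0 rose (median -0.52), including Hrk (-1.20), Fosl2 (-1.10) and Npas4 (-0.91); 5 of the 14 listed genes are also on the immediate early list.

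Lists of other cell types and pathways were also counted. Indirect pathway markers fell in 6 of 7 (median -0.68), including Gpr6 (-0.86), while the direct pathway list held 3 lower and 2 higher genes, Isl1 (0.29) among the higher. Striatal interneuron markers fell in 9 of 16, with Vip at -1.07 and Cck at -0.75. Cortical projection neuron markers, which could enter with neighbouring tissue, fell in 7 of 12, with Neurod6 at -0.95 and Slc17a7 (a vesicular glutamate transporter) at -0.92. Within wild type and within DREAM+/-, Cck ran in the same order of arrays as the mean of these cortical markers. Within R6/2 and within R6/2 x DREAM+/- the orders differed. Whether the Cck and Vip changes came from cortical tissue was not tested. Oligodendrocyte markers fell in 6 of 14, with Ugt8a at -0.60 and Mal at -0.50. Astrocyte markers fell in 8 of 15 and rose in 2, with Agt at -0.58 and S100b at 0.44, and Gfap read -0.20 (adjusted p = 0.159). Interferon and MHC class I genes rose in 6 of 16 and fell in 0, with Ifit3 at 0.64 and B2m at 0.44. Kv4 channel complex genes, a list that holds Kcnip3, fell in 4 of 9 and rose in 1, with Kcnip2 at -0.79. Homeobox and developmental factors rose in 2 of 7 and oxidative phosphorylation genes in 6 of 32, with 1 of the latter lower.

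These gene lists were tested with camera against all other genes, with adjustment over 168 tests. Adjusted p was 9.49e-25 for the medium spiny neuron list, 1.74e-17 for immediate early genes, 5.98e-08 for calcium handling, 7.09e-08 for the clock, 2.63e-07 for cholesterol synthesis, 7.85e-06 for glutamate genes and 3.22e-05 for both neurotrophin genes and DREAM targets. It was 3.36e-06 for indirect pathway markers, 6.36e-06 for interneurons, 0.000109 for cortical markers, 0.000544 for oligodendrocytes and 0.00202 for astrocytes. Interferon genes gave 0.00297, Kv4 genes 0.0235 (0.0735 without Kcnip3), oxidative phosphorylation 0.0416 and homeobox factors 0.0421. With an estimated correlation among genes, only the indirect pathway list kept its call (adjusted p = 0.0334 with an estimated correlation). Adjusted p = 0.0647 with an estimated correlation for the medium spiny neuron, immediate early, clock, cholesterol, interneuron, astrocyte and DREAM target lists. Adjusted p with an estimated correlation was 0.0715 for neurotrophin, 0.170 for calcium, 0.185 for glutamate and homeobox, 0.201 for Kv4, 0.268 for cortical, 0.282 for interferon, 0.316 for oligodendrocyte and 0.374 for oxidative phosphorylation genes. Adjusted over the list alone, 30 medium spiny neuron, 20 immediate early, 18 calcium handling, 13 glutamate, 12 interneuron, 11 clock, 10 DREAM target, 9 astrocyte and 7 indirect pathway genes were lower. Interferon genes then had 7 higher, astrocyte genes 2 higher, and oxidative phosphorylation genes 4 higher and 1 lower, and the remaining called lists had the counts found over all genes.

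The other 11 lists did not pass. Camera adjusted p was 0.0555 for the ATF6 and unfolded protein response list, with 8 of 34 genes lower and 2 higher. Within it, Atf6 fell by 0.51 on the log2 scale, Ddit3 by 0.26 and Xbp1 by 0.24, while Hspa5 read -0.18 and did not pass (adjusted p = 0.0817). Without R6/2 replicate 3, Xbp1 no longer passed (adjusted p = 0.0513). GABA system genes gave 0.0575, microglia markers 0.206, direct pathway markers 0.258, neighbouring forebrain 0.287, cytosolic heat shock 0.324, p53 and apoptosis 0.355, choroid plexus 0.417, oligodendrocyte precursors 0.637, sex-linked genes 0.824 and vascular markers 0.965. The sex-linked list joins Xist with Y-linked genes, which differ with sex in opposite directions. Camera tests for 1 direction, so its value for this list does not show that the sexes were balanced. Under quantile normalization the homeobox call was lost (adjusted p = 0.0654), and with arrays shifted to a common median the oxidative phosphorylation call was lost (adjusted p = 0.0576). The homeobox call was also lost without wild-type replicate 2 or 4 or R6/2 replicate 1 (adjusted p up to 0.0693), and the oxidative phosphorylation call without wild-type replicate 4 or R6/2 replicate 4 (up to 0.0849).

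**Figure D3:**
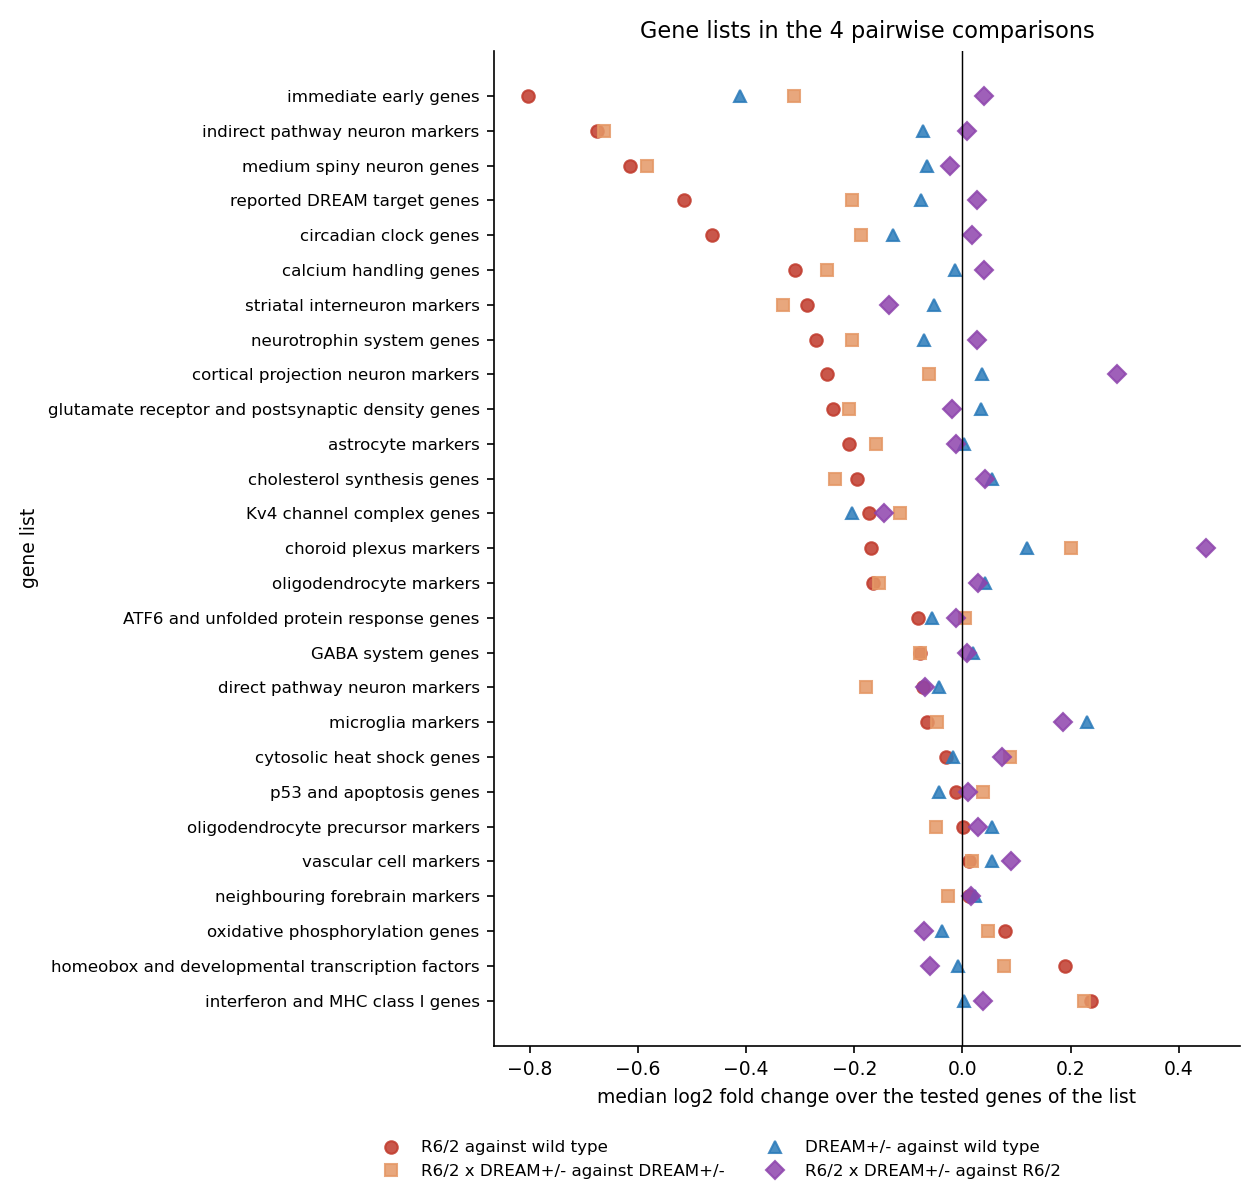
Median log2 fold change (x axis) over the tested genes of 27 gene lists (y axis) in the 4 pairwise comparisons, 1 symbol per comparison. Medium spiny neuron genes lie at -0.62 and -0.58 in the R6/2 comparisons, and immediate early genes at -0.80 in R6/2 against wild type and -0.41 in DREAM+/- against wild type.

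The same question was asked on the DREAM+/- background. In R6/2 x DREAM+/- against DREAM+/-, 30 of 32 medium spiny neuron genes fell and 0 rose (median -0.58). Cnr1 changed by -0.94, Penk by -0.85, Ppp1r1b by -0.75, Drd2 by -0.71, Pdyn by -0.68 and Drd1 by -0.51. Ryr1 changed by -1.95, Crh by -1.84, Egr2 by -1.64, Abi3bp by -1.59, Ddit4l by -1.52 and Scn4b by -1.27. Abi3bp and Crh lay under the brightness filter in R6/2 x DREAM+/- (5.39 and 5.17), and Tnnt2 in DREAM+/- (5.76). Sfmbt2 rose by 1.09, Pcdh20 by 0.81 and Tnnt2 by 0.80. Atf6 fell by 0.55 on the log2 scale (adjusted p = 0.00102). Bdnf fell by 0.20 (adjusted p = 0.0478), a call lost on leaving out any 1 of 7 arrays (adjusted p up to 0.144).

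Limma called 1944 genes here, 920 higher and 1024 lower, of which 1463 were called with the same sign in R6/2 against wild type and 0 with the opposite sign, where independent lists would share 246 and 248. The 2 R6/2 comparisons share no arrays, and their log2 changes correlated across genes at r = 0.798 (0.000346 in simulations of unchanged groups); genes are not independent replicates. Immediate early genes fell in 11 of 23 (median -0.31), clock genes in 7 of 17, cholesterol genes in 12 of 20, calcium handling genes in 13 of 28 with 1 higher, and interneuron markers in 11 of 16. Cortical projection neuron markers passed in 1 of 12, Lamp5 at -0.18 (camera adjusted p = 0.208), and Kv4 genes were not called (0.0644). Camera called 14 of 28 lists, 13 lower and interferon and MHC class I genes higher (6 of 16, median 0.22). The medium spiny neuron list gave adjusted p = 4.67e-30, or adjusted p = 0.0647 with an estimated correlation, and only indirect pathway markers (5 of 7 lower, adjusted p = 1.97e-05) kept their call (adjusted p = 0.0337 with an estimated correlation).

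The other called lists of this comparison gave camera adjusted p of 2.29e-09 for cholesterol synthesis, 2.1e-08 for interneurons, 9.06e-08 for calcium handling, 5.61e-07 for glutamate genes, 8.29e-07 for immediate early genes and 5.82e-06 for oligodendrocyte markers. They were 4.53e-05 for clock genes, 7.78e-05 for neurotrophin genes, 0.000519 for interferon genes, 0.00187 for astrocyte markers, 0.00329 for DREAM targets and 0.0268 for GABA system genes. Adjusted p with an estimated correlation was 0.0647 for cholesterol and astrocyte, 0.0594 for interneuron, 0.172 for calcium, 0.152 for glutamate, 0.209 for immediate early, 0.195 for oligodendrocyte, 0.109 for clock, 0.0783 for neurotrophin, 0.201 for interferon, 0.17 for DREAM target and 0.185 for GABA genes. Adjusted over the list alone, 30 medium spiny neuron, 16 calcium handling, 14 cholesterol, 13 immediate early, 11 interneuron, 11 glutamate, 9 astrocyte, 8 clock and 7 neurotrophin genes were lower, and 3 calcium handling, 2 astrocyte, 1 immediate early, 1 DREAM target and 7 interferon genes were higher. Of 24 glutamate genes 10 fell, of 14 DREAM targets 6 fell and 1 rose, of 14 oligodendrocyte markers 6 fell, of 15 astrocyte markers 5 fell and 1 rose, of 10 neurotrophin genes 4 fell, and of 16 GABA system genes 3 fell. Without DREAM+/- replicate 2 the GABA call was lost (adjusted p = 0.0503).

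Whether the R6/2 effect differed with DREAM dose was tested by the interaction of both factors. No single gene passed: limma called 0 of 13011, with 898 at an unadjusted p under 0.05 where chance gives 651. Array weights, trended and robust variance and an Xist covariate also called 0, quantile normalization called 1 and the 60th percentile filter 3. The Xist covariate mostly marks R6/2 replicate 1 (6.49 against 11.04 to 12.16 in the other arrays), so it does not adjust for the Y-linked levels. Mid1 read 5.86 in R6/2, under the brightness filter. The lowest adjusted p were those of Mid1 and Tnni1 (0.0578) and Nr4a2 (0.0587), with interaction values of 1.51, -0.61 and 0.93 (log2). With the 60th percentile filter these 3 genes passed (adjusted p = 0.0384, 0.0384 and 0.0456). Without wild-type replicate 2 or R6/2 replicate 4, 2 genes passed, and without wild-type replicate 1, DREAM+/- replicate 4 or R6/2 x DREAM+/- replicate 4, 1 gene passed. In simulated data the interaction test recovered 26.0% of changes of 0.3 (log2), 78.0% of 0.5 and 100% of 1. Those data held enough changed genes to give 160 calls, against 0 here, which makes an adjusted p under 0.05 easier to reach. In the real data Mid1 at 1.51 did not pass. The simulated shares therefore overstate what the real test could find, and larger interactions as well as small ones may be missed.

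The interaction was also tested for gene lists. Immediate early genes had interaction values above 0, with a median of 0.43 (camera adjusted p = 8.57e-19, adjusted p = 0.0647 with an estimated correlation), and 14 of 23 passed when adjusted over the list alone. Fosl2 read 0.89 (adjusted p = 0.502). Egr2 read 1.05 (adjusted p = 0.496), with R6/2 at 5.80 and R6/2 x DREAM+/- at 5.98, near the brightness filter of 5.944, so its value follows in large part the lower level in DREAM+/- (7.62) than in wild type (8.49). The mean of the list was 0.76 below wild type in R6/2 striatum and its R6/2 change on the DREAM+/- background was -0.30, a ratio of 0.397. Most of this difference lay in the lower list mean of DREAM+/- against wild type (-0.40, exact permutation p = 0.0286), while R6/2 x DREAM+/- against R6/2 was 0.06 (exact permutation p = 0.486), so the ratio does not show a higher level in the crossed animals than in R6/2. In the same 2 comparisons the DREAM target list read -0.28 and -0.02 and the clock list -0.19 and -0.04. For the immediate early list, the difference of the R6/2 changes between both backgrounds had an exact two-sided permutation p of 0.0143, which adjustment over 28 lists took to 0.343. Camera also called cortical markers (median 0.18, adjusted p = 1.97e-05), clock genes (0.14, 0.000251), cytosolic heat shock genes (0.08, 0.000478), DREAM targets (0.16, 0.00724), the ATF6 and unfolded protein response list (0.06, 0.0352) and choroid plexus markers (0.37, 0.0493). Adjusted p with an estimated correlation was 0.211, 0.149, 0.198, 0.185, 0.408 and 0.672 in that order, so none of the 7 kept its call. Under quantile normalization the ATF6 list was at 0.0533. The choroid plexus and ATF6 calls were each lost on leaving out any 1 of 7 arrays, with adjusted p up to 0.95 without R6/2 replicate 4 for choroid plexus markers and up to 0.0948 without R6/2 x DREAM+/- replicate 1 for the ATF6 list. The exact permutation p of the difference of list means was 0.0245 for heat shock genes, 0.0706 for DREAM targets and 0.103 for both cortical and clock genes, which adjustment took to 0.343, 0.576 and 0.576.

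A score per array summed the R6/2 change over the 4606 genes whose R6/2 effect, averaged over both backgrounds, passed limma. It was 0.28 ± 0.02 in R6/2 and 0.23 ± 0.03 in R6/2 x DREAM+/- (log2, mean ± SD, n = 4), where wild type is 0 by construction and DREAM+/- lay at 0.01 ± 0.02. The R6/2 effect on the DREAM+/- background was 0.802 of that on the normal background. R6/2 x DREAM+/- lay below R6/2 with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays can give, and DREAM+/- against wild type had p = 0.486. The difference of differences, -0.06, had an exact permutation p of 0.0204. The separation is narrow: the lowest R6/2 array and the highest R6/2 x DREAM+/- array both read 0.263. On leaving out each array in turn the ratio stayed between 0.778 and 0.878, but the exact permutation p was under 0.05 in only 4 of 16 cases and reached 0.314 without R6/2 x DREAM+/- replicate 3. With arrays shifted to a common median, the 60th percentile filter or the mean of all probe sets, the exact permutation p was 0.0857. With the signature taken from genes called on the DREAM+/- background alone the ratio was 0.998, and from genes called on the normal background 0.669. Each of these choices favours genes whose R6/2 effect came out large on its own background, which pushes the former ratio up and the latter down.

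**Figure D4:**
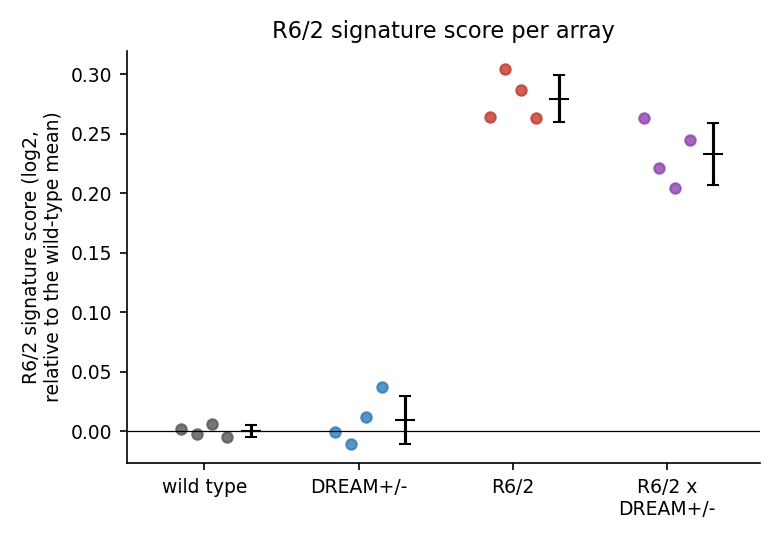
R6/2 signature score per array (y axis, log2 relative to the wild-type mean) in the 4 genotypes, 1 point per array, with mean and SD beside the points (n = 4). R6/2 arrays lie between 0.263 and 0.304 and R6/2 x DREAM+/- arrays between 0.204 and 0.263.

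DREAM+/- against wild type asks what the lower DREAM dose changed without the transgene. The Y-linked gene Eif2s3y read 7.51 to 8.05 in DREAM+/- and 6.16 to 7.80 in wild type. A different share of male RNA may therefore enter this comparison, which was not tested. On the R6/2 background Eif2s3y read 6.23 to 7.42 in R6/2 x DREAM+/- and 6.57 to 8.91 in R6/2. Immediate early genes fell in 8 of 23 and rose in 0 (median -0.41), and adjusted over the list alone 15 of 23 were lower. Npas4, a neuronal activity-regulated factor, fell from 8.39 ± 0.39 to 7.57 ± 0.11 (log2, n = 4, adjusted p = 0.00482), and Arc changed by -0.74, Fosb by -0.63 and Egr4 by -0.51. Fos read -0.86 and did not pass (adjusted p = 0.078). Of 14 DREAM targets 2 fell, Npas4 and Junb (-0.71), and 0 rose, though DREAM is described as a repressor; adjusted over the list alone 6 fell. Microglia markers rose in 4 of 15 and fell in 0, with Fcrls at 0.83, C1qb (a complement subunit) at 0.41 and C1qc at 0.26. Adjusted over the list alone 8 rose and 1 fell, and Aif1 read 7.52 to 7.67 against 7.81 to 7.90 in wild type. Fcrls is among the large DREAM+/- changes for which variants of another strain stay possible in the closing observations. Besides Kcnip3, the Kv4 channel partners Dpp10 (-0.28) and Dpp6 (-0.23) fell, so that 2 of the 8 genes of the complex other than Kcnip3 were lower. The medium spiny neuron list held 1 higher and 0 lower genes of 32 (camera adjusted p = 0.455), with Pdyn at -0.33 and Ppp1r1b at -0.30 not passing (adjusted p = 0.0808 and 0.0582).

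Limma called 479 genes, 208 higher and 271 lower, and 326 higher and 196 lower with the arrays shifted to a common median, which turns the balance. Changes outside the lists included Rbm45 at -2.35, Tmem87a at -2.25, Cap1 at -2.06, Magi1 at -1.34 and Abhd1 at -1.19, and upward Pttg1 at 1.38, Acer3 at 1.35 and Ang at 1.07. All of these are among the large DREAM+/- changes for which variants of another strain stay possible in the closing observations. The MHC class I gene H2-K1, also among those large changes, rose by 0.99 and B2m by 0.36, Per3 fell by 0.49 (4 of 6 probe sets with that sign) and Hspa1a by 0.45. A rise of MHC class I with lower DREAM dose thus cannot be told apart from a strain variant for H2-K1. Camera called the immediate early list (adjusted p = 1.35e-08), microglia (7.61e-07), Kv4 (0.000339, or 0.0304 without Kcnip3), clock (0.000782), vascular (0.00195), cholesterol (0.0235), oligodendrocyte (0.0268) and DREAM target (0.0361) lists. None kept its call, with adjusted p = 0.170, 0.0752, 0.0741, 0.172, 0.142, 0.336, 0.542 and 0.288 with an estimated correlation in that order. Without any 1 of wild-type replicate 2 or DREAM+/- replicates 1 to 4 the count of genes was 284, 295, 280, 315 and 288. Calls of C1qc, Dpp10, Hspa1a, B2m and Cap1 were each lost without at least 1 array (adjusted p up to 0.129, 0.0706, 0.053, 0.0589 and 0.068). The oligodendrocyte call was lost without wild-type replicate 1, 2 or 3 (adjusted p up to 0.122), the DREAM target call without wild-type replicate 2 or 3 (up to 0.0908), and the cholesterol call without wild-type replicate 4 or DREAM+/- replicate 1 (up to 0.0924).

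**Figure D5:**
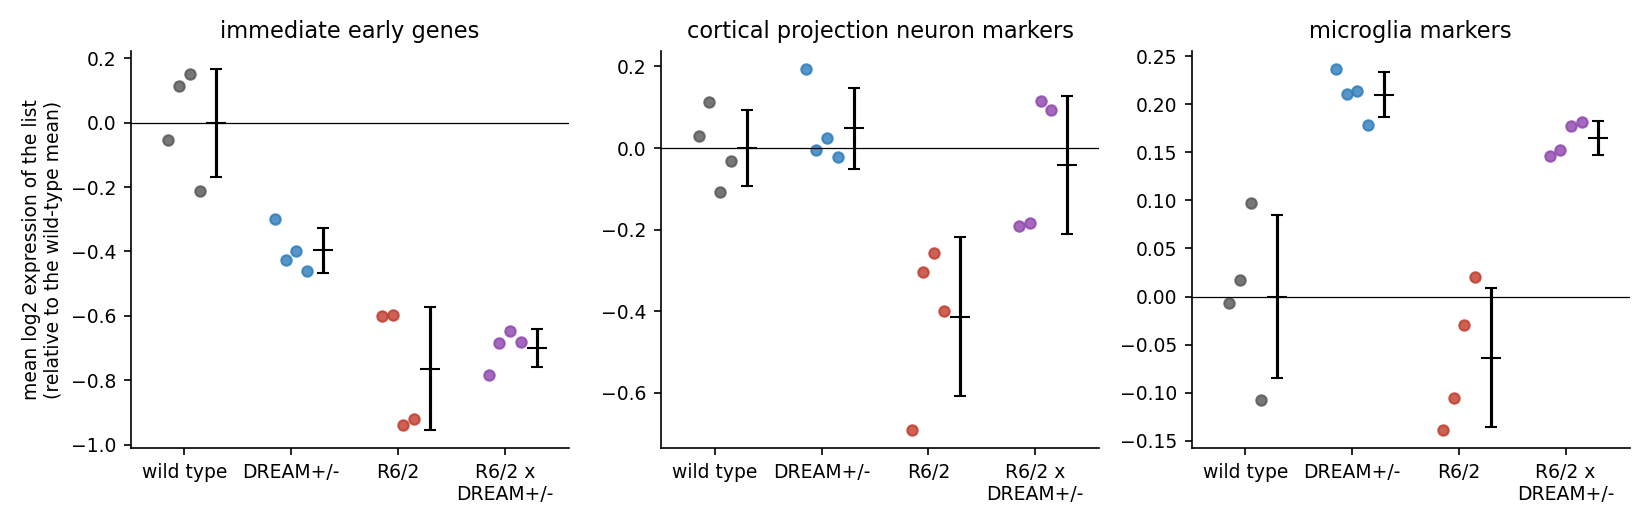
Mean log2 expression of 3 gene lists per array relative to the wild-type mean (y axes, each with its own range) in the 4 genotypes, with mean and SD beside the points (n = 4). Immediate early genes average -0.76 in R6/2, cortical markers -0.41 in R6/2, and microglia markers 0.21 in DREAM+/-.

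In R6/2 x DREAM+/- against R6/2, the comparison that asks what a lower DREAM dose changed in R6/2 striatum, the medium spiny neuron list was not called as a group. Of its 32 genes 2 rose, 3 fell and 27 did not pass (median and mean -0.02, camera adjusted p = 0.532 with the opposite sign). Cnr1 read 0.21, Drd1 0.23 and Penk -0.03 (adjusted p = 0.0911, 0.0887 and 0.859), while Pdyn fell by 0.34 and Ppp1r1b by 0.30 on the log2 scale (adjusted p = 0.0344 and 0.0288). Microglia markers rose in 5 of 15 and fell in 0 (median 0.19), with Fcrls at 0.73, C1qb at 0.55 and C1qc at 0.39; adjusted over the list alone 9 rose and 1 fell. The astrocyte gene Gfap rose by 0.53 (adjusted p = 0.00334), in a list with 3 higher, 1 lower and 11 genes not passing (median -0.01, mean 0.05, camera adjusted p = 0.167). In the Kv4 complex Kcnip3, Dpp6 (-0.36), Kcnip1 (-0.33, 3 of 4 probe sets with that sign) and Kcnip4 (-0.20) fell, 4 of 9 genes, and without Kcnip3 the list was not called (camera adjusted p = 0.291).

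Cortical projection neuron markers rose in 6 of 12 and fell in 0 (median 0.29), with Slc17a7 at 1.02 (SE 0.16, adjusted p = 0.000789), Neurod6 at 0.87, Tbr1 at 0.56 and Fezf2 at 0.33. Slc17a7 averaged 8.34 in R6/2 x DREAM+/-, 8.23 in wild type and 7.32 in R6/2. In other lists, Nrgn rose by 0.38, Dlgap2 by 0.61, Grm3 by 0.58 and Gria3 by 0.24 in the glutamate list (5 of 24 higher, 0 lower, median -0.02 and mean 0.08), Ryr2 by 0.32 in the calcium list (4 higher, 1 lower of 28), and Cck by 0.71 and Vip by 0.60 in the interneuron list, which held 2 higher, 1 lower and 13 genes not passing (median -0.14, camera adjusted p = 0.479, lower). The glutamate list was not called (camera adjusted p = 0.0517). Immediate early genes rose in 4 of 23 and fell in 1, with Nr4a2 at 0.97, Klf10 at 0.37 and Npas4 at -0.65. Of 14 DREAM targets 3 fell and 0 rose (median 0.03, mean -0.02, camera adjusted p = 0.736). Cholesterol synthesis genes rose in 8 of 20 and fell in 2, with Cyp51 at 0.33 (2 of 3 probe sets with that sign) and Idi1 at 0.26. Atf6 read 0.15, Hspa5 0.19 and Bdnf 0.07, and none of them passed (adjusted p = 0.337, 0.0959 and 0.497). The ATF6 and unfolded protein response list held 1 higher and 1 lower gene of 34 (camera adjusted p = 0.421).

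Limma called 1819 genes, 693 higher and 1126 lower, and 980 higher and 815 lower with the arrays shifted to a common median, which turns the balance. Kcne2 rose by 2.68, Tmem267 by 2.35, Mid1 by 2.15 (2 of 3 probe sets with that sign), Pttg1 by 2.02 and Acer3 by 1.61, and Rbm45 changed by -2.70, Cap1 by -2.49, Tmem87a by -1.93, Abhd1 by -1.31 and Magi1 by -1.06. For each of these genes variants of another strain stay possible in the closing observations. Kcne2 and Mid1 averaged 5.68 and 5.86 in R6/2, under the brightness filter of 5.944, so background sets part of these changes. Within the DREAM+/- group Kcne2 read 6.40 to 9.15 in the same order of arrays as the choroid plexus marker means, -0.762 to 0.890, and within R6/2 x DREAM+/- 7.68 to 9.13 in the order of means from -0.292 to 0.887. Within wild type and within R6/2, where Kcne2 read 5.04 to 6.65 and 5.30 to 6.12, the orders differed. H2-K1 (3 of 4 probe sets with that sign) rose by 0.81 and Per3 fell by 0.70 on the log2 scale (5 of 6), and the vascular genes Abcc9 (2 of 3) and Kdr rose by 0.33 and 0.20. For H2-K1, which read 8.02 to 9.18 within R6/2, a strain variant stays possible as well. Camera called the cortical (adjusted p = 5.82e-06), microglia (1.97e-05), vascular (0.00706), choroid plexus (0.013), cholesterol (0.014), calcium handling (0.04), Kv4 (0.0421) and heat shock (0.0493) lists, with only Kv4 lower. None kept its call, with adjusted p = 0.193, 0.129, 0.18, 0.632, 0.311, 0.582, 0.265 and 0.483 with an estimated correlation in that order. Adjusted over the list alone, 6 cortical, 3 vascular, 2 heat shock and 6 calcium handling genes were higher, and 4 Kv4, 3 calcium handling and 1 heat shock gene were lower. Of 19 heat shock genes 16 did not pass over all genes. Of 13 choroid plexus genes 0 passed, though 3935 of all genes had an unadjusted p under 0.05, and the choroid and heat shock calls were lost with a common median (adjusted p = 0.0551 and 0.0524). The calcium handling rise rested on R6/2 x DREAM+/- replicate 3: without it the list mean was 0.015 rather than 0.08 and the call was lost (adjusted p = 0.334), as it was without R6/2 replicate 2 (0.0536) or R6/2 x DREAM+/- replicate 2 (0.0584). The choroid plexus call was lost without R6/2 replicate 4 or R6/2 x DREAM+/- replicate 1 (adjusted p up to 0.44). The heat shock call was lost without R6/2 replicate 1, 3 or 4 or R6/2 x DREAM+/- replicate 4 (up to 0.177), and the Kv4 call without R6/2 replicate 1, 3 or 4 or R6/2 x DREAM+/- replicate 1 (up to 0.0601). The count of genes was 1067 without R6/2 replicate 4, 1096 without R6/2 x DREAM+/- replicate 2, and 1067 in a fit of only the 8 arrays compared. The calls of Pdyn, Ppp1r1b, Vip, Kdr, Kcnip4, Kcnip1 and Tbr1 were each lost without at least 1 array (adjusted p up to 0.101, 0.0885, 0.0885, 0.065, 0.0813, 0.0653 and 0.0551).

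Averaged over R6/2 status, 2878 genes differed with the DREAM+/- genotype, 977 higher and 1901 lower, and 1502 higher and 1241 lower with a common median. How far a different share of male RNA enters this count was not tested. Tmem87a fell by 2.09, Rbm45 by 2.53 and Kcnip3 by 1.72 on the log2 scale, and Tmem267 rose by 1.93 and Acer3 by 1.48. Apart from Kcnip3, these genes are among the large changes for which variants of another strain stay possible. Microglia markers rose in 9 of 15 and fell in 1, with Fcrls at 0.78 and C1qb at 0.48 (camera adjusted p = 1.81e-06, adjusted p = 0.0822 with an estimated correlation). Pdyn, Ppp1r1b and Dpp6 fell by 0.34, 0.30 and 0.30 on the log2 scale (adjusted p = 0.0037, 0.00248 and 1.44e-05), and Gfap rose by 0.43. Camera called 8 of 28 lists, Kv4 lower (5 of 9 with Kcnip3, adjusted p = 0.00656, but 0.0931 without Kcnip3) and 7 higher: cortical (4 of 12, 0.000227), vascular (4 of 13, 0.00111), cholesterol (7 of 20 with 2 lower, 0.00706), glutamate (6 of 24, 0.0389), choroid plexus (0 of 13, 0.0416), oligodendrocyte (2 of 14, 0.0493) and microglia. None kept its call, with adjusted p = 0.165, 0.289, 0.124, 0.268, 0.542, 0.672 and 0.574 with an estimated correlation in that order. With a common median the choroid plexus, oligodendrocyte and glutamate calls were lost (adjusted p = 0.182, 0.0567 and 0.055), and 5 lists were called without wild-type replicate 1. The glutamate call was lost without R6/2 x DREAM+/- replicate 3, where the list mean was 0.04 rather than 0.06 (adjusted p = 0.164), and without wild-type replicates 1 or 3 or DREAM+/- replicate 2. The choroid plexus call was lost on leaving out any 1 of 7 arrays (adjusted p up to 0.304 without R6/2 replicate 4) and the oligodendrocyte call any 1 of 9 (up to 0.114 without wild-type replicate 3). The DREAM+/- changes with and without the transgene, which share no arrays, correlated across genes at r = 0.705, with 328 genes called with the same sign and 1 with the opposite sign, where independent lists would share 34.5 and 32.4.

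The overlap of the R6/2 change with the DREAM+/- change in R6/2 animals was also measured. Of genes called in both comparisons, 645 went in opposite directions and 91 in the same direction, where independent lists would share 235 and 228. The R6/2 arrays enter both comparisons with opposite sign, which by itself favours opposite directions. No such count was simulated or split, so these counts alone do not show a reversal. The log2 changes of all tested genes correlated at r = -0.312, but both comparisons use the R6/2 arrays and unchanged groups give -0.499 in simulation. The covariance was -0.0125 against a simulated -0.00367, and with the R6/2 arrays split between the comparisons r lay between -0.268 and -0.122 over 6 splits. In DREAM+/- against wild type, the covariance with the R6/2 change was 0.004 against a simulated 0.00368.

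Genes near Kcnip3 changed more often with the DREAM+/- genotype than others. Within 20 Mb of Kcnip3 on its chromosome, 73 of 243 tested genes (30.0%) passed for the averaged effect, against 2792 of 12704 elsewhere (22.0%), an odds ratio of 1.52 (95% interval 1.14 to 2.02, two-sided Fisher's exact p = 0.00379). The odds ratio was 1.43 within 10 Mb and 1.27 within 40 Mb (Fisher's exact p = 0.0376 and 0.0191). For genes that passed with a change of at least 0.7 (log2) it was 2.72 within 20 Mb (95% interval 0.542 to 8.46), with 3 of 243 genes near and 58 of 12704 elsewhere, and did not pass (Fisher's exact p = 0.107). Positions came from GRCm38.p6 for 99.52% of tested genes and served only to find neighbours.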

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

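None of the tests in this part was chosen after its result was seen. The values below are of single arrays that lay far from the other 3 of their genotype, and of gene lists whose R6/2 change differed with the DREAM+/- genotype.

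Array means of each gene list and levels of sex-linked genes were compared within each genotype with Dixon's test, relative to the wild-type mean for lists (log2). In 140 groups of 4 arrays, 8 had an array far from the others, where chance flags about 1 in 20 groups, or 7. Choroid plexus markers averaged -1.37 in R6/2 replicate 4 against 0.0802 to 0.36 in the other R6/2 arrays. Xist read 6.49 in R6/2 replicate 1 against 11.58 to 11.95. In R6/2 x DREAM+/- replicate 3 the sex-linked genes averaged -0.39 against 0.123 to 0.203, Eif2s3y read 6.23 against 7.34 to 7.42, and Kv4 channel complex genes averaged -0.353 against -0.537 to -0.519. Indirect pathway markers averaged -0.0568 in wild-type replicate 4 against 0.0146 to 0.0218. In DREAM+/- replicate 4 blood markers averaged 0.0475 against -0.103 to -0.0825, and homeobox and developmental factors 0.139 against 0.0357 to 0.0514. No explanation of these arrays was tested.

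For 7 gene lists camera found an R6/2 change that differed between the DREAM+/- and the normal background. The median interaction values were 0.43 for immediate early genes such as Egr2 and Nr4a2, 0.373 for choroid plexus markers, 0.183 for cortical projection neuron markers such as Slc17a7, 0.164 for DREAM targets such as Fosl2, 0.14 for circadian clock genes, 0.0775 for cytosolic heat shock genes and 0.0588 for the ATF6 and unfolded protein response list. With an estimated correlation 0 of the 7 were called, and 5 of the DREAM targets are also immediate early genes. The choroid plexus value rests on R6/2 replicate 4: without it the list's mean interaction was -0.0164 rather than 0.381. In R6/2 the cortical markers averaged -0.691, -0.303, -0.257 and -0.400 on the 4 arrays, and in R6/2 x DREAM+/- -0.190, -0.184, 0.116 and 0.0921. Whether these cortical values reflect neurons in striatum or neighbouring tissue was not tested.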

How the results depend on the processing

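The tests without both arrays that stand apart, with the cortical marker score as a covariate and of the Kv4 list without Kcnip3 were chosen after the data were examined.

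The count for R6/2 against wild type stayed within 1.5 times 3307 under each alternative but the 1.5-fold threshold. With that threshold added, 286 genes passed in R6/2 against wild type, 136 in R6/2 x DREAM+/- against R6/2, 102 in DREAM+/- against wild type, 164 in R6/2 x DREAM+/- against DREAM+/- and 100 for the averaged DREAM+/- effect, fewer by construction. With every probe set counted on its own the R6/2 x DREAM+/- against R6/2, DREAM+/- against wild type and averaged counts were 2894, 746 and 4611, since more features were tested. Array weights gave 899 in DREAM+/- against wild type, and only the 8 arrays compared gave 1067 in R6/2 x DREAM+/- against R6/2. Each fit of 8 arrays estimates the spread from fewer arrays. Why this count moved was not tested. For the interaction, the 60th percentile filter gave 3 genes and quantile normalization 1; for the latter the cause was not tested.

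The signature ratio was 0.819 with the 60th percentile filter, 0.817 with the mean of all probe sets and 0.802 with a common median, each with an exact permutation p of 0.0857. It was 0.818 for averaged effects of at least 1.5-fold (exact permutation p = 0.171) and 0.998 for genes called on the DREAM+/- background (p = 1), against 0.669 for genes called on the normal background (p = 0.0286). Each choice selects genes with large effects on its own background, which moves these ratios up and down. Without both arrays that stand apart it was 0.851 (exact permutation p = 0.2), where 3 against 3 arrays cannot reach 0.05.

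Camera with an estimated correlation called 1, 0, 0, 1, 0 and 0 lists in R6/2 against wild type, R6/2 x DREAM+/- against R6/2, DREAM+/- against wild type, R6/2 x DREAM+/- against DREAM+/-, the interaction and the averaged effect. Fry called 5 in R6/2 x DREAM+/- against R6/2 and 2 for the interaction. With Kcnip3 taken out of the Kv4 list the counts were 16, 6, 8, 14, 6 and 6. No filter gave 11 interaction lists and a common median 5 lists for the averaged effect; the cause was not tested.

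Leaving out each array in turn gave 280 to 625 genes in DREAM+/- against wild type, 1067 to 2708 in R6/2 x DREAM+/- against R6/2, 2692 to 3151 in R6/2 against wild type, 1304 to 2306 in R6/2 x DREAM+/- against DREAM+/-, 0 to 2 for the interaction and 2222 to 3783 for the averaged effect. The highest values for R6/2 x DREAM+/- against R6/2, against DREAM+/- and the averaged effect came without R6/2 x DREAM+/- replicate 3. The signature ratio ranged from 0.778 to 0.878, and lists called for the averaged effect from 5 to 10.

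The arrays share only a replicate number: 11 of 24 same-number pairs had a residual correlation above 0.1 (range -0.413 to 0.287). In 11 of 24 cases an array correlated best with its own number, where chance gives 6, and replicate 1 was above 0.1 in 5 of 6 pairs of groups, so some pairing is not excluded. With a replicate block the counts were 3339, 1709, 434, 1946, 0 and 2842 in the order given for lists, and the lists called 17, 6, 8, 14, 7 and 7. The block lost the heat shock (adjusted p = 0.0527) and Kv4 (0.0543) calls in R6/2 x DREAM+/- against R6/2, oxidative phosphorylation in R6/2 against wild type (0.0527) and oligodendrocyte markers for the averaged effect (0.0543), and added the ATF6 list in R6/2 against wild type (0.0469).

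Of 536 gene results, 443 passed, and over the alternatives 10847 of 11572 values kept direction and call, 664 lost a call, 51 gained one and 10 reversed. With the mean of all probe sets Atp5g1 reversed to -0.131 in R6/2 against wild type, 0.359 in R6/2 x DREAM+/- against R6/2, -0.0787 in R6/2 x DREAM+/- against DREAM+/- and 0.333 averaged. With probe sets of less specific design left out Gfra2 reversed to 0.0125 in R6/2 against wild type and 0.025 in R6/2 x DREAM+/- against DREAM+/-, Trem2 to -0.102 in R6/2 x DREAM+/- against R6/2, -0.055 in DREAM+/- against wild type and -0.0787 averaged, and Rbm28 to -0.065 in DREAM+/- against wild type. Another probe set then stood for the gene. Signal near background limits dim genes, and 13011 of 18193 genes were bright enough to be tested.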

Other observations

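The tests of Kcnip3 against the loss of gene copies, of neighbours on chromosomes and of the share near Kcnip3 among large changes were chosen only after the result was seen, and so was the condition that a signature ratio lie more than 1 SE under 0.95.

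Kcnip3 fell by more than 1 on the log2 scale in arrays labelled DREAM+/-, a larger fall than 1 lost gene copy would give in proportion. The highest upper 95% bound over both probe sets and both R6/2 states was -1.35, which argues against that proportional reading as the whole cause. Over the 8 DREAM+/- arrays the brighter probe set read no lower than 7.43 (log2), above the brightness filter of 5.944, and the dimmer read 5.24 to 5.85, under it on each array. Loss of both copies cannot be told apart from loss of 1, since the deleted part of the gene is not given and the brighter probe set could lie outside it. A response of the remaining copy was not tested.

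Besides Kcnip3, 63 genes changed by at least 0.7 (log2) for DREAM+/- averaged over R6/2 status, 44 higher and 19 lower. They included Rbm45, Tmem87a, Acer3 and the microglia markers Fcrls and Cx3cr1. Of 61 with a position, 22 had another within 2 Mb, against a mean of 9.61 in 10000 random sets, of which a share of 0.0022 had as many. The 61 genes lay on 17 chromosomes, with 10 on chromosome 7, Acer3 among them, and 6 on chromosome 2, Tmem87a and Rbm45 among them. Of the 61, 3 lay within 20 Mb of Kcnip3 (4.92%, exact upper 95% bound 13.7%). This argues against DNA of the donor strain around Kcnip3 as the only source. It does not argue against such DNA as a source for the 3 genes that lie there. Other probe sets of the 63 genes passed the same way in 31 of 55 cases (56.4%), against 63 of 78 (80.8%) for 112 genes of like size for R6/2 (Fisher's exact p = 0.0035). Variants of another strain under probe sets or near genes may thus contribute to part of the 63 changes, and a response to DREAM dose stays open.

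The R6/2 changes were smaller in sum on the DREAM+/- background, with a ratio of 0.802 (jackknife SE 0.0711). Without any 1 of the R6/2 x DREAM+/- arrays the ratio stayed at or below 0.878 (SE 0.0628 on the remaining arrays), which lies under 0.95 by little more than 1 SE, so a single array is argued against only weakly. With the cortical marker score as a covariate the ratio was 0.805 (SE 0.0854). The score read -0.691 to -0.257 in R6/2 arrays and -0.190 to 0.116 in R6/2 x DREAM+/- arrays, so it separates the groups compared. It also holds genes that fell in R6/2, 7 of 12. The covariate thus rests on scatter within groups of 4 arrays, and cortical tissue as the whole cause is argued against only weakly. The exact permutation p of 0.0286 is under 0.05 but was kept in only 4 of 16 cases on leaving out an array, so chance stays a weakly excluded candidate explanation. The medium spiny neuron list alone gave an exact permutation p of 0.857 for R6/2 x DREAM+/- against R6/2, which leaves open whether those neurons share in any attenuation.

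Chance can be excluded at the 5% level for the counts of genes of the 4 pairwise comparisons, since 1 of 35 splits of the same arrays, the real 1, gave as many in each. The real counts were 3307 in R6/2 against wild type, 1819 in R6/2 x DREAM+/- against R6/2, 479 in DREAM+/- against wild type and 1944 in R6/2 x DREAM+/- against DREAM+/-, and the highest of the other splits gave 8, 1, 3 and 1. For the averaged DREAM+/- effect, 1 of 100 splits gave as many as 2878, and the highest other gave 732. For the interaction the real count was 0, so 100 of 100 splits had to give as many, which says nothing about chance. The highest other gave 1611 genes, from a draw that nearly exchanged DREAM labels in 1 R6/2 state, which points to a structure of the samples, the DREAM+/- genotype itself.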
